A study of Homo sapiens with 23 samples.

How the data were processed

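KGN cells, an established line of human ovarian granulosa cells, were exposed to a mixture of polybrominated diphenyl ethers (PBDEs) at 0, 1, 5 or 20 µM for 48 h, per the labels' protocols. RNA from 23 samples was measured, 6 samples each at 0, 1 and 20 µM and 5 at 5 µM. Per the labels' protocols, 100 ng of total RNA was labelled with Cy3 and 600 ng of labelled material was hybridised to each single-colour Agilent array. The group of each sample was taken from its title, and replicates were numbered within a group in the order of the records, so a number only names an array and pairs nothing.

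The deposited scanner files hold linear spot intensity, extracted with Agilent Feature Extraction 11.5.1.1 per the submitters' processing notes and per the file headers. The processed signal in these files is already background-subtracted by that software, per the file headers, and is not normalised between arrays. The deposited value table holds log2 values of the same arrays, and how the authors made them is not given in the sources used here. Set against the scanner files over 13444 bright probes, each of its 23 columns matched 1 array at a correlation of 0.994 to 0.999 across probes, while the second best array reached at most 0.821. The table was on a log2 scale in the same direction as the scanner values, with slopes of 0.994 to 1.00 against the matching array, with each array scaled and each row centred on its median. The array that matched was the named one for 2 columns and another one for 21, and for 18 of these it had another dose. All 23 columns matched the arrays in scan order, while the column names run in dose order. The scanner files were therefore used throughout, and the value table under its own column names was kept as an alternative. The medians of its columns were −0.05, 0.00, 0.06, 0.00, −0.04 and 0.09 for the columns named 0 µM. They were 0.00, 0.08, −0.05, 0.07, 0.06 and 0.17 for those named 1 µM. They were −0.11, 0.00, −0.08, 0.00 and −0.03 for those named 5 µM, and −0.09, −0.08, −0.02, −0.13, 0.13 and −0.01 for those named 20 µM.

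For each array, log2 of the processed signal was taken and the array's own 75th percentile over 58717 non-control spots was subtracted. Spots the scanner software marked as outliers were left out, at most 1.12% of the spots of an array, and no spot was saturated. Spots of 1 probe were averaged, giving 50599 probes. A probe was kept where it was well above background on every array of at least 1 dose group, which left 25127 probes. Probes were named through the RefSeq accessions in the files and a table of the GRCh38.p14 annotation used for names only: 29033 probes matched 20992 genes, and 21566 probes kept the identifier of the file. For genes with several kept probes, which were 4012, the probe with the highest mean over all arrays stood for the gene. This gave 19876 genes for testing, 14382 of them with a gene symbol.

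Each gene was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per dose group over all 23 arrays, the moderated variance of eBayes and Benjamini-Hochberg adjustment over all genes. Genes with an adjusted p under 0.05 were called changed. Each dose was compared with 0 µM, and adjacent doses with each other. A further limma fit took a slope on the dose rank, in log2 units per dose step. Gene groups were 32 lists with 698 genes in all, and each list with at least 5 measured genes was tested with camera at a preset correlation between genes of 0.01. The named protein-coding genes with a value on every array entered that test, which was repeated with the correlation estimated from the data. For each list the adjusted p of its members was also computed over the list alone. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

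The 32 lists covered steroidogenesis, cholesterol synthesis and uptake, fatty acid synthesis and LXR, PPAR and fatty acid oxidation, NRF2 targets, antioxidant enzymes, glutathione S-transferases, AHR targets, CAR and PXR targets, the ATF4 amino acid response, ER chaperones, heat shock, metallothioneins, p53 targets, the mitotic cell cycle and DNA replication. They also covered the BCL2 family and caspases, hypoxia and glycolysis, NF-κB and inflammation, the interferon response, oxidative phosphorylation, lysosome and autophagy, the thyroid hormone response, the estrogen response, granulosa identity, cAMP and immediate early genes, and extracellular matrix and TGF-β. Markers of leukocytes, of endothelial, epithelial and neuronal cells, and of theca and stroma made up the rest. The groups, lists, tests and most alternatives were fixed before the data were examined.

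The genes named in the text followed a rule fixed at the same time. For each comparison with 0 µM it takes up to 10 changed genes with the largest rise and up to 10 with the largest fall, with a gene symbol, well above background on every array of 1 of the groups and with the same sign on all 3 slides. It adds, from each list, the 4 measured members with the smallest p, and 17 genes of steroid production, oxidative stress, xenobiotic response and growth. Where fewer than 5 genes pass in a comparison, the 5 with the smallest p are given as not passing. Not every member the rule allows is printed, and any gene named outside it is said to be so.

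The procedure was tested on simulated data with 23 arrays and 19741 genes, 200 of them changed in each of 5 draws. For 20 µM against 0 µM it recovered 38.2% of genes changed 1.5-fold, 79.7% of those changed 2-fold and 97.3% of those changed 4-fold, with 7.20 false calls per draw on average. The simulated genes and arrays were independent, so these rates may not hold for the real arrays. Without changes, 5 against 0 µM gave 957 simulated genes at an unadjusted p under 0.05 on average, where the real arrays gave 83.

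The files hold 1 scan session per slide, so slide and scan are 1 batch here. Each of the 3 slides held arrays of every dose. Arrays of a dose lay at the same places on every slide, so an effect of a place cannot be told apart from that of its dose. Slide was tested as a fixed and as a random block and within each slide. Row and column of the array were added to slide as fixed effects, the sets of 1 slide and 1 row were used as a block, and each row was fitted by itself. The other alternatives were quantile normalisation, median scaling, normexp background correction with an offset of 50, other filters and probe rules, other variance models, other sources of values and leaving out each array in turn. The files carry the median signal of a spot and not its mean, so normexp used the median signal with the background median. The alternatives added after the data had been seen were leaving out the 4 arrays lowest on the first principal component, the mean of the mitotic list as a covariate, and components of the residuals as covariates. Spots give no depth as read counts do, and the number of arrays limits the precision.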

Results

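KGN cells are an established line of human granulosa cells. In the ovarian follicle, granulosa cells surround the oocyte and make estradiol, and results in a line need not hold for them. The KGN cells were exposed for 48 h to a mixture of PBDEs, a family of brominated flame retardants, and their messenger RNA was measured on whole-genome arrays. The mixture was modelled on the PBDEs found in fluid from ovarian follicles, and the question was what it does to steroid production and to oxidative stress. There were 6 arrays at 0 µM, 6 at 1 µM, 5 at 5 µM and 6 at 20 µM, on 3 slides that each held every dose. The 75th percentile of the processed signal lay between 345.6 and 597.8 units, and 53.8 to 61.4% of spots were well above background on an array. Arrays of 1 dose correlated at 0.972 to 0.993 across genes and arrays of different doses at 0.968 to 0.994, and no 2 arrays were identical. The labels do not say whether the arrays of a dose came from separate cultures, so p-values here measure only the spread between these arrays. That spread may be technical. For the mean of the mitotic list, the SD between arrays within a dose was 1.04 on the log2 scale. Slide accounted for 2.9% of its variance, row for 0.3% and column for 2.6%, which argues against these as the source for that list. The main fit pairs no arrays.

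The comparison of 20 µM with 0 µM asked which genes the highest dose changed. Of 19876 genes, 16 rose and 9 fell. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose most, by 2.74 ± 0.34 on the log2 scale (SE, n = 6 and 6), which is 6.68-fold (limma, adjusted p = 0.000621). CPT1A, which admits long-chain fatty acids to mitochondria, rose 1.84-fold (log2 0.88 ± 0.12, adjusted p = 0.00251). CYP1A1, the classic target of the aryl hydrocarbon receptor, rose 3.13-fold (log2 1.65 ± 0.24, adjusted p = 0.00251). The Wnt receptor FZD8 rose 3.01-fold (adjusted p = 0.00382) and SHISA2, a modulator of Wnt and FGF signalling, 3.96-fold (adjusted p = 0.013).

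The other named rises were smaller. FAM167A rose 2.23-fold, SPOCD1 1.80-fold, the chromatin protein HMGA1 1.73-fold and the cofilin phosphatase SSH1 1.72-fold, with adjusted p between 0.00472 for HMGA1 and 0.0209 for SSH1. RND3 rose 1.73-fold with the highest adjusted p of the called genes (limma, 0.0469), and its call was not followed over the other settings. A second probe of SSH1 gave a log2 fold change of 0.26 ± 0.19 where the one used gave 0.79 ± 0.15. Among the genes that fell, the atypical MAP kinase MAPK4 was 5.22-fold lower (log2 −2.38 ± 0.41, adjusted p = 0.0124) and was well above background on only 3 of the 6 arrays at 20 µM. The galectin LGALS12 was 3.11-fold lower (log2 −1.64 ± 0.26, adjusted p = 0.00503). NEBL, an actin-binding protein, was 2.52-fold lower and well above background on 2 of the 6 arrays at 20 µM. LDHD, which oxidises D-lactate, was 1.90-fold lower (adjusted p = 0.0432), the semaphorin SEMA4G 1.62-fold lower (adjusted p = 0.0354) and LNPK, a protein of the endoplasmic reticulum, 1.60-fold lower. The smallest p of all belonged to an uncharacterised transcript listed as XR_245037, named here after its values were seen, with a log2 fold change of −1.33 ± 0.12 and an adjusted p of 1.73e-06.

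All 25 genes had the same sign on each of the 3 slides, though each dose kept its places on them. The genes were chosen on these same arrays, so this agreement adds little. With slide as a block 30 genes were called. Within a slide, with 2 arrays a dose, limma called 0 genes on each (1114, 1339 and 661 at an unadjusted p under 0.05, where 994 are expected by chance), with ANGPTL4 higher by 3.62, 2.21 and 2.39 on the 3 slides and CYP1A1 by 1.96, 1.33 and 1.65. With slide, row and column of the array as fixed effects 3 genes were called, with only the 2 groups in the fit 3, without the filter on dim probes 16, with median scaling 17 (14 up and 3 down), and without 0 µM replicate 1 or 20 µM replicate 2, 15 and 16. LDHD kept its call under 17 of 45 settings and SEMA4G under 21, and leaving out 1 array ended the call of LDHD for 15 arrays (adjusted p 0.052 to 0.124), of SEMA4G for 11 (0.0505 to 0.109), of SSH1 for 3 (0.0547 to 0.073) and of SHISA2 and NEBL for 0 µM replicate 1 (0.0504 and 0.0505). Normexp ended the calls of MAPK4 (adjusted p = 0.0505) and SHISA2 (adjusted p = 0.117).

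**Figure D1:**
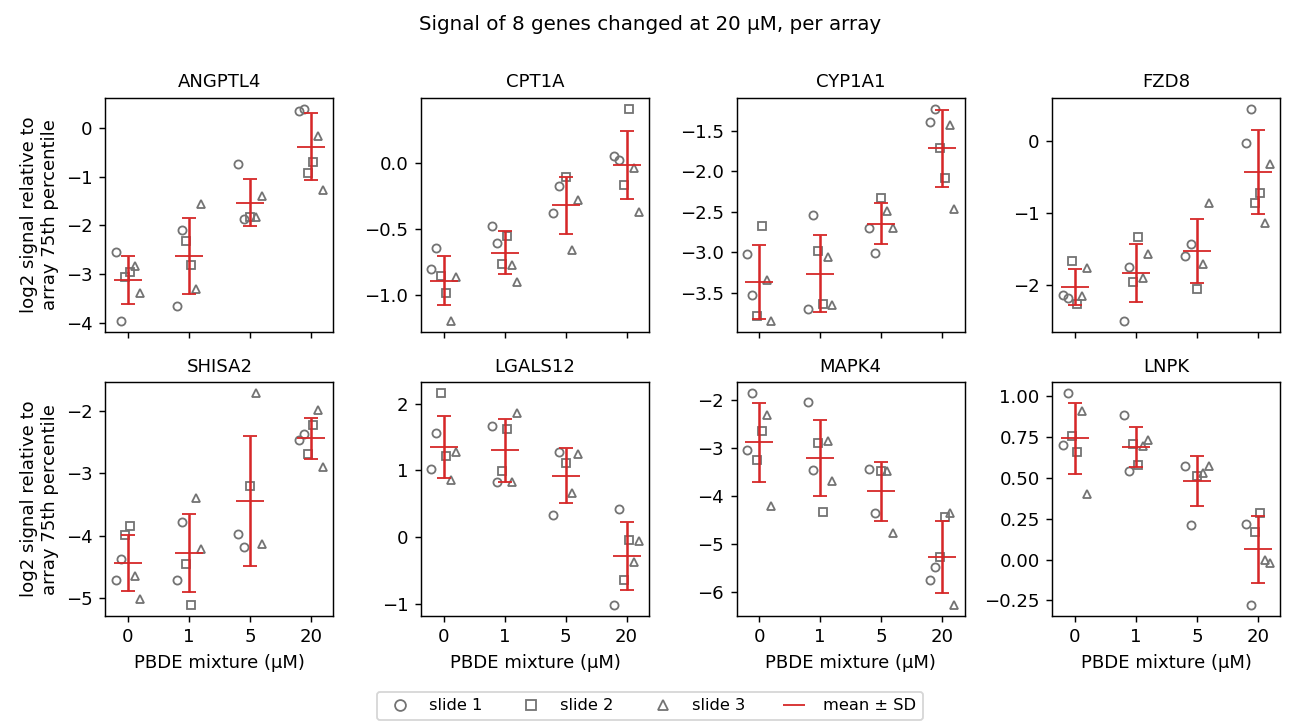
Signal of 8 genes on each array, as log2 relative to the array's 75th percentile, against the dose of the PBDE mixture in µM. Symbols are arrays by slide, and the red bars are the mean ± SD of a dose. ANGPTL4 went from −3.13 ± 0.49 at 0 µM to −2.62 ± 0.78, −1.54 ± 0.49 and −0.39 ± 0.68 at 1, 5 and 20 µM.

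Genes of steroid production were not called at 20 µM. STAR, which brings cholesterol into mitochondria, had a log2 fold change of −0.37 ± 0.35, CYP11A1, which cleaves the cholesterol side chain, −0.33 ± 0.23, HSD17B1 −0.13 ± 0.20, HSD17B8 −0.63 ± 0.24 and the transcription factor NR5A1 −0.08 ± 0.12. STAR measured 7.98 ± 0.59 at 0 µM and 7.61 ± 0.77 at 20 µM (log2, SD, n = 6 each). Of 21 measured genes of steroidogenesis, 16 were lower and 5 higher and 0 passed the test, and the list was not shifted (camera, adjusted p = 0.174). HSD3B2, HSD3B1 and CYP19A1, the aromatase, were not well above background: HSD3B2 passed on 5 of the 23 arrays, HSD3B1 on 1, and the 3 probes of CYP19A1 on 5, 2 and 6. Within slide 3 the direction turned for STAR (log2 0.06), CYP11A1 (0.15) and HSD17B1 (0.21), and NR5A1 changed sign with median scaling (0.01).

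The single genes of oxidative stress were not called either. The log2 fold changes at 20 µM were 0.41 ± 0.15 for catalase (CAT), 0.61 ± 0.42 for SOD2, 0.16 ± 0.31 for NQO1 and 0.15 ± 0.24 for the heme oxygenase HMOX1. SOD1 differed by 0.01 ± 0.13 and GPX1 by 0.00 ± 0.12, with signs that turned under several settings. The 24 measured antioxidant enzymes were not shifted as a group (adjusted p = 0.376), nor were 16 glutathione S-transferases (adjusted p = 0.177). Targets of NRF2, the transcription factor that answers oxidants, were shifted up: 23 of 26 were higher, with a median of 0.16 on the log2 scale (camera, adjusted p = 0.00017, and adjusted p = 0.442 with an estimated correlation). None of the 26 passed singly. SRXN1 and GSR, both of thiol repair, had log2 fold changes of 0.40 and 0.36, the NRF2 partner MAFG had 0.34 and thioredoxin, TXN, 0.24.

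Lipid handling genes were shifted at 20 µM in both directions by camera at its preset correlation, and only the upward shift passed with an estimated one. Of 17 genes of PPAR and fatty acid oxidation, 13 were higher, ANGPTL4 and CPT1A rose over all genes, and 5 rose when adjusted over the list alone. These included ACAA2, the last enzyme of mitochondrial beta-oxidation (log2 0.39, adjusted p = 0.00148 over the list alone), and CREB3L3 (1.22, adjusted p = 0.00278 over the list alone). The list's adjusted p was 5.7e-07 by camera and 0.0307 with an estimated correlation. Genes of fatty acid synthesis and LXR were shifted down, with 16 of 17 lower and a median of −0.32 (adjusted p = 2.19e-05, and adjusted p = 0.442 with an estimated correlation). Over that list alone, 3 fell: the cholesterol exporter ABCG1 (−0.59), MID1IP1 (−0.70) and SREBF1 (−0.89), the gene of a transcription factor for lipid synthesis. Genes of cholesterol synthesis and uptake were lower in 24 of 26 cases with a median of −0.30 (adjusted p = 0.00116, and adjusted p = 0.606 with an estimated correlation). None passed singly.

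At 20 µM, genes of hypoxia and glycolysis gave the smallest list p at camera's preset correlation, and PPAR genes the smallest with an estimated one. Hypoxia and glycolysis genes were lower in 26 of 28 cases with a median of −0.37 (camera, adjusted p = 2.14e-11, and adjusted p = 0.235 with an estimated correlation), and 10 fell when adjusted over the list alone. Examples were the kinase PDK1 (−0.53), which restrains pyruvate oxidation, carbonic anhydrase CA9 (−0.77), BNIP3 (−0.59) and the glycolytic enzyme PGAM1 (−0.44), with adjusted p of 0.0306 for PDK1 and 0.0356 for the others over the list alone. Genes of NF-κB and inflammation were higher in 16 of 18 cases with a median of 0.44 (adjusted p = 1.56e-06, and adjusted p = 0.372 with an estimated correlation). Over the list alone 6 rose, among them the cytokines IL6 (1.11, adjusted p = 0.00126), IL1B (0.91, adjusted p = 0.00819) and CXCL8 (1.04, adjusted p = 0.0252) and the subunit gene NFKB1 (0.43, adjusted p = 0.00349). Interferon response genes were lower in 19 of 22 cases (adjusted p = 0.00514, and adjusted p = 0.606 with an estimated correlation), with IFIT1 at −0.64.

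Targets of the aryl hydrocarbon receptor were higher in 7 of 10 cases (camera, adjusted p = 0.0234, and adjusted p = 0.165 with an estimated correlation). CYP1A1 rose over all genes, CYP1B1 rose over the list alone (log2 0.62, adjusted p = 0.0242), and TIPARP had 0.52. Genes of the ATF4 amino acid response were higher in 27 of 34 cases (adjusted p = 0.036, and adjusted p = 0.442 with an estimated correlation). The member that passed over the list alone was VLDLR, which fell (−0.69, adjusted p = 0.0219), while STC2 had 1.29 and PPP1R15A 0.65. Camera called 9 lists in all, 9 with slide as a block and 8, 7 and 10 within the slides, and 1, the PPAR list, with an estimated correlation. Within slide 2 the NF-κB list turned down (adjusted p = 0.889), within slide 3 cholesterol (adjusted p = 0.0204) and interferon (adjusted p = 0.252) turned up, and leaving out 1 array ended the calls of cholesterol and interferon (0 µM replicate 2, adjusted p = 0.184 and 0.185), AHR (0 µM replicate 3, 0.0549; 20 µM replicate 5, 0.215) and, for 7 arrays, ATF4.

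Single members passed over their list alone in several lists that were not shifted. In heat shock genes (19, adjusted p = 0.2) the co-chaperone HSPH1 rose over all genes (1.65-fold, adjusted p = 0.0209, a call lost without any 1 of 5 arrays, with adjusted p 0.0582 to 0.0731), and over the list alone 3 rose, HSPH1, HSPE1 (log2 0.31, adjusted p = 0.012) and 1 more, and 2 fell, the small heat shock genes HSPB8 (−0.75) and HSPB1 (−0.44), with an adjusted p of 0.0331 each. Among 21 genes of granulosa identity (adjusted p = 0.556) the inhibin subunit INHA fell over the list alone (−0.78 ± 0.16, adjusted p = 0.00217) and missed the threshold over all genes (adjusted p = 0.0622), and GATA4 had −0.33. The autophagy receptor SQSTM1 rose over the list alone (0.60, adjusted p = 0.00687) among 27 lysosome and autophagy genes (adjusted p = 0.289), and KLF9 rose (0.64, adjusted p = 0.0282) among 12 thyroid hormone response genes (adjusted p = 0.289).

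Growth and cell identity lists were not shifted at 20 µM by camera. The adjusted p was 0.505 for 30 mitotic genes, 0.823 for 27 of DNA replication, 0.826 for 25 p53 targets and 0.239 for 23 of the BCL2 family and caspases. MKI67, a marker of dividing cells, had −0.11 ± 0.34, with a sign that turned for a mean of all its probes (0.16), and the p53 target CDKN1A −0.40 ± 0.20. It was 0.759 for 23 ER chaperones, 0.289 for 8 metallothioneins, 0.802 for 5 CAR and PXR targets, 0.921 for 37 genes of oxidative phosphorylation, 0.978 for 19 of the estrogen response, 0.224 for 27 of cAMP and immediate early response and 0.984 for 25 of extracellular matrix and TGF-β. Markers of other cell types were not shifted: 0.823 for leukocytes, endothelium and theca and stroma, and 0.177 for epithelial and neuronal markers, with TUBB3 lower over its list alone (−0.38, adjusted p = 0.0264). The median, the mean and the direction of the test differed in sign for DNA replication (0.03, −0.02, up), CAR and PXR (0.01, −0.04, down), extracellular matrix (−0.01, 0.04, down), endothelial markers (0.00, 0.03, down) and oxidative phosphorylation (−0.01, 0.00, up).

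**Figure D2:**
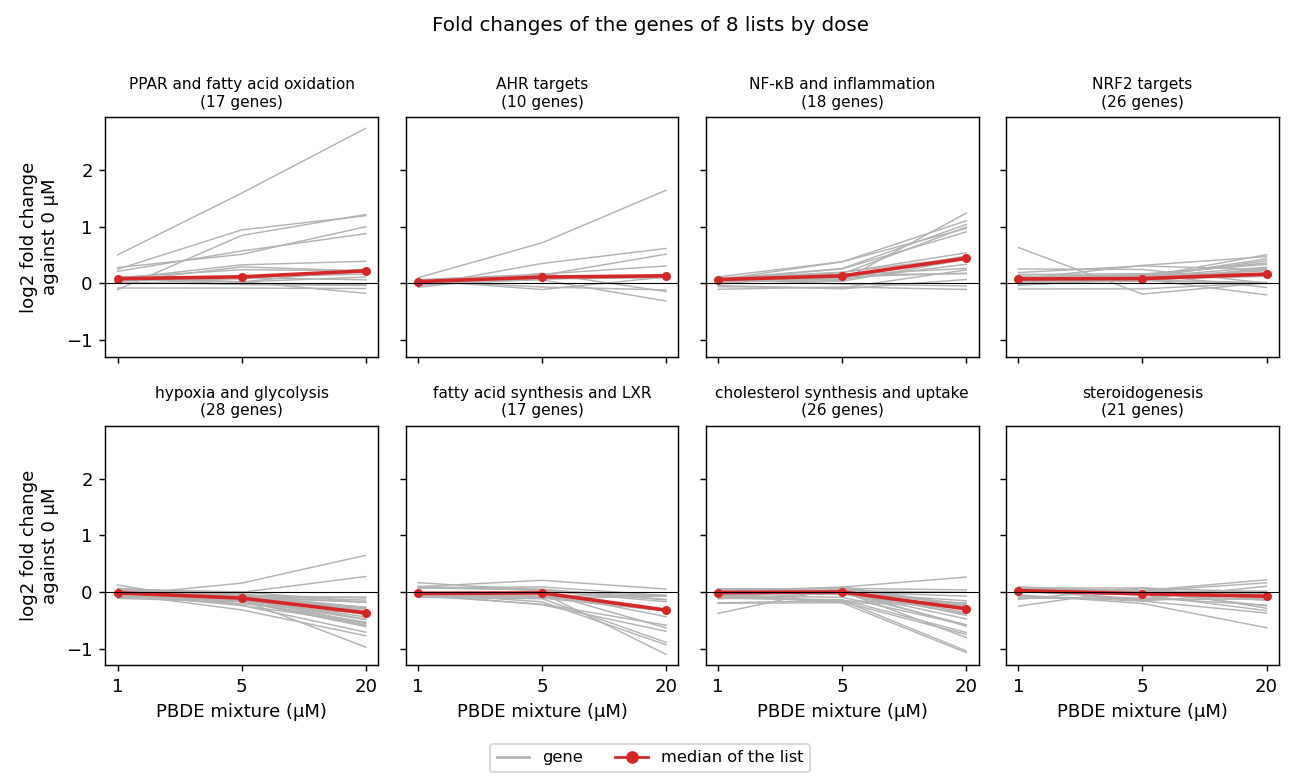
Log2 fold change against 0 µM of each measured gene (grey) of 8 lists and the median of the list (red), against the dose of the PBDE mixture in µM, evenly spaced. The median of hypoxia and glycolysis genes went from −0.01 at 1 µM to −0.11 and −0.37 at 5 and 20 µM, and that of PPAR and fatty acid oxidation from 0.08 to 0.12 and 0.22.

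At 5 µM, genes of PPAR and fatty acid oxidation stood out as a group against 0 µM. Of 17, 14 were higher, with a median of 0.12 (camera, adjusted p = 4.5e-16, and adjusted p = 0.00026 with an estimated correlation). Camera weighs a list against the spread of the other genes' statistics, and that spread was narrow at 5 µM. Its p is then smaller for the same shift and does not rank 5 µM above 20 µM. At 20 µM the mean log2 fold change of the list was 0.494, and at 5 µM it was 0.33. ANGPTL4 had 3.02-fold and CPT1A 1.49-fold higher signal, and ACAA2 a log2 fold change of 0.33 ± 0.09 (n = 5 and 6). These 3 rose when adjusted over the list alone (limma, adjusted p = 0.00194, 0.00194 and 0.0119) and did not pass over all genes (adjusted p = 1). Hypoxia and glycolysis genes were lower in 26 of 28 cases (adjusted p = 6.85e-06, and adjusted p = 0.562 with an estimated correlation), and NRF2 targets higher in 24 of 26 (adjusted p = 5.95e-05, and adjusted p = 0.562 with an estimated correlation).

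No gene was called at 5 µM over all genes (limma, 0 called, 83 at an unadjusted p under 0.05, where 994 are expected by chance). With so few the test was stricter than its threshold says, so 0 calls do not show that nothing changed. After ANGPTL4, CPT1A and ACAA2, the smallest p came with TBC1D32 (log2 −0.70 ± 0.22, not passing) and SH3GL3 (−0.28 ± 0.09, not passing). CYP1A1 had 0.72 ± 0.25 and CYP1B1 0.35 ± 0.21, STAR −0.16 ± 0.36, CYP11A1 −0.05 ± 0.24, HSD17B1 0.06 ± 0.21, NR5A1 0.01 ± 0.12, HMOX1 0.08 ± 0.25, NQO1 0.07 ± 0.32, CAT 0.17 ± 0.16, SOD1 0.04 ± 0.14, SOD2 0.10 ± 0.44, GPX1 0.03 ± 0.13, CDKN1A −0.06 ± 0.20 and MKI67 0.12 ± 0.35. The steroidogenesis list was not shifted (adjusted p = 0.282). Camera called 3 lists, 4 with slide as a block and 8, 9 and 11 within the slides, where PPAR had a p of 0.0158, 0.000904 and 0.000891, and limma called 0, 44 and 0 genes within them, slide 2 holding a single array at 5 µM. NRF2 targets turned down within slide 1 (adjusted p = 0.126) and lost the call without 0 µM replicate 6 or 5 µM replicate 3 (adjusted p = 0.0527 and 0.389), and hypoxia genes turned up within slide 3 (adjusted p = 0.0231) and lost it without 5 µM replicate 2 (adjusted p = 0.294).

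At 1 µM the shifts were small. Genes of PPAR and fatty acid oxidation were higher in 15 of 17 cases with a median of 0.08 (camera, adjusted p = 0.000747, and adjusted p = 0.239 with an estimated correlation). NRF2 targets were higher in 23 of 26 (adjusted p = 0.00204, and adjusted p = 0.98 with an estimated correlation), heat shock genes in 18 of 19 (adjusted p = 0.0167, and adjusted p = 0.621 with an estimated correlation) and genes of oxidative phosphorylation in 33 of 37 (adjusted p = 0.0167, and adjusted p = 0.98 with an estimated correlation). ANGPTL4 had a log2 fold change of 0.51 ± 0.34 and CPT1A of 0.21 ± 0.12.

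No gene was called at 1 µM (limma, 0 called, 59 at an unadjusted p under 0.05, where 994 are expected by chance). As at 5 µM, the test was stricter than its threshold says. Camera's p for a list is likewise smaller than a wider spread of the other genes would give. The smallest p came with TRARG1 (log2 −0.51 ± 0.18), SLC39A5 (−0.47 ± 0.17), KLK9 (−0.64 ± 0.23), TTC41P (−0.59 ± 0.22) and TBC1D32 (−0.55 ± 0.21), none of them passing (adjusted p = 1). STAR had 0.06 ± 0.35, CYP11A1 0.09 ± 0.23, HSD17B1 −0.25 ± 0.20, NR5A1 0.09 ± 0.12, HMOX1 0.04 ± 0.24, NQO1 −0.03 ± 0.31, CAT 0.09 ± 0.15, SOD1 0.06 ± 0.13, SOD2 0.16 ± 0.42, GPX1 0.07 ± 0.12, CYP1A1 0.10 ± 0.24, CYP1B1 −0.04 ± 0.20, CDKN1A 0.08 ± 0.20 and MKI67 −0.05 ± 0.34. The steroidogenesis list was not shifted (adjusted p = 0.827), with a median of 0.02 and a test pointing down. Camera called 4 lists, 4 with slide as a block, 1, 10 and 9 within the slides and 1 with quantile normalisation, and within slide 2 NRF2 targets (adjusted p = 0.516) and heat shock genes (adjusted p = 0.564) turned down. PPAR genes had a p of 4.53e-05, 0.325 and 0.516 within slides 1, 2 and 3, with 9 of 17 higher on slides 2 and 3. Leaving out 1 array ended the call of NRF2 targets for 3 arrays, of heat shock genes for 5 and of oxidative phosphorylation for 7, and that of PPAR genes for 0.

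Along the dose order, 19 genes rose and 10 fell, and 21 of these 29 were also called at 20 µM against 0 µM. ANGPTL4 rose by 0.93 ± 0.11 per dose step on the log2 scale (limma, adjusted p = 0.000184), CYP1A1 by 0.56 ± 0.08 (adjusted p = 0.00221) and CPT1A by 0.30 ± 0.04 (adjusted p = 0.000279). MAPK4 fell by 0.79 and LGALS12 fell by 0.53 per step. ACAA2 (0.14, adjusted p = 0.0325) and IL6 (0.36, adjusted p = 0.0405) passed here and not in the comparison of 20 µM with 0 µM over all genes. The trend gave 0 genes within each slide and each row, 18 with median scaling, 12 without the filter, 17 with slide, row and column, and 17, 17, 14, 17 and 16 without replicate 1, 2, 3, 4 or 6 of 20 µM.

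Between adjacent doses, some gene lists were shifted by camera at its preset correlation. From 1 to 5 µM, PPAR and fatty acid oxidation genes were shifted up (camera, adjusted p = 2.5e-07, and adjusted p = 0.0201 with an estimated correlation) and hypoxia and glycolysis genes down (adjusted p = 0.00398, and adjusted p = 0.803 with an estimated correlation). From 5 to 20 µM, hypoxia and glycolysis genes were shifted down (adjusted p = 7.02e-07), as were fatty acid synthesis (adjusted p = 3.11e-05), cholesterol (adjusted p = 0.00226) and interferon genes (adjusted p = 0.0159), and NF-κB genes up (adjusted p = 1.8e-05). With an estimated correlation these gave an adjusted p of 0.584 for hypoxia, fatty acid synthesis and NF-κB and 0.689 for cholesterol and interferon. PPAR genes were not shifted between 5 and 20 µM (adjusted p = 0.142). limma called 0 genes from 1 to 5 µM and 1 from 5 to 20 µM. At an unadjusted p under 0.05 there were 88 and 817, where 994 are expected by chance. With only 88, camera's p for a list from 1 to 5 µM is also smaller than a wider spread would give. The 1 gene was XR_245037 with −0.97 ± 0.12 (limma, adjusted p = 0.00119). It was not called with slide, row and column in the fit or with only the 2 groups. Within slide 2, where 5 µM had 1 array, 77 and 70 genes were called, and within slides 1 and 3, 1 and 0 for 1 to 5 µM and 0 and 0 for 5 to 20 µM.

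Fold changes at the 3 doses share their controls. Across genes, which are not independent replicates, those at 20 and 5 µM correlated at 0.486 where unchanged groups against the same controls gave 0.476, those at 20 and 1 µM at 0.353 (0.502) and those at 5 and 1 µM at 0.471 (0.476). The covariances were 0.0148, 0.0097 and 0.0077, against 0.027, 0.0272 and 0.027 for unchanged groups. The values for unchanged groups were simulated with independent arrays, and the simulated covariances are too high if the arrays came in sets that each held every dose. With the controls split 3 and 3 the correlations were −0.175 and 0.029, −0.284 and −0.081, and −0.317 and −0.314. The calls at 20 µM shared 0 genes with those at 5 or 1 µM, where 0 were called and 0 shared genes are the expectation for independent lists.

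Arrays of 1 dose differed widely in genes of cell division while the doses did not. The mean of the mitotic list on an array ranged from −1.66 to 1.13 at 0 µM, −1.60 to 1.14 at 1 µM, −1.65 to 1.54 at 5 µM and −1.36 to 1.12 at 20 µM, and the dose means lay between −0.05 and 0.04. The SD within a dose was 1.04 for mitotic genes, 0.65 for cholesterol genes, 0.35 for interferon genes and 0.12 for PPAR and fatty acid oxidation genes. The dose means of the last list were −0.23, −0.12, 0.10 and 0.26.

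**Figure D3:**
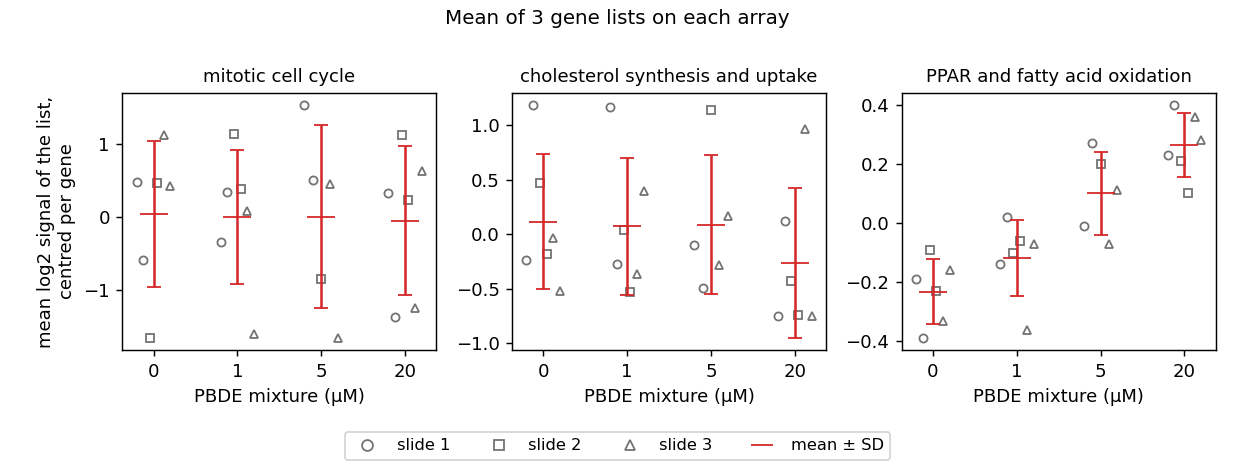
Mean log2 signal of 3 gene lists on each array, each gene centred on its mean, against the dose of the PBDE mixture in µM. Symbols are arrays by slide, and red bars are the mean ± SD of a dose. The mitotic list spans −1.66 to 1.54 with dose means near 0, and the PPAR list moves from −0.23 to 0.26.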

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

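The values below stood apart from the other arrays of their dose by Dixon's test, whose limits were set before the data were examined, and no explanation of them was tested. Of 308 sets of values, 23 held such an array, and chance gives about 1 in 20, which is 15.4 sets. All values of genes are log2 signals relative to the array's 75th percentile.

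Among genes changed at 20 µM, FAM167A was −2.27 on 1 array at 1 µM, with the others between −1.70 and −1.42. LNPK was 0.21 on 1 array at 5 µM (others 0.51 to 0.58), HAUS6 was 1.13 on 1 array at 5 µM (others 0.99 to 1.02), SSH1 was −0.05 on 1 array at 0 µM (others −0.32 to −0.22) and LDHD was −2.70 on 1 array at 20 µM (others −2.10 to −1.84).

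Genes of hypoxia and glycolysis stood apart on single arrays. At 0 µM, replicate 6 had 1.98 for PDK1 (others 2.48 to 2.76), 6.18 for BNIP3 (others 6.81 to 7.08) and 5.17 for PGAM1 (others 5.74 to 5.89). At 20 µM, CA9 was 1.42 on replicate 5 (others 2.26 to 2.75) and PGAM1 was 4.83 on replicate 6 (others 5.23 to 5.43).

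Other members of gene lists stood apart as well. The interferon gene IFIT1 was 3.06 on 0 µM replicate 2 (others 1.96 to 2.30) and 2.24 on 20 µM replicate 5 (others 1.36 to 1.66), and the mean of the interferon list was 0.68 on 5 µM replicate 3 (others −0.28 to −0.04). These arrays are among the 4 lowest on the first principal component, which are 1 per dose. ABCG1 was −0.92 on 5 µM replicate 3 (others −1.28 to −1.18), VLDLR −0.14 on 1 µM replicate 4 (others 0.48 to 0.80), STC2 3.08 on 20 µM replicate 3 (others 4.24 to 4.77) and SQSTM1 6.13 on 1 µM replicate 5 (others 6.49 to 6.70). HSD17B1 was −4.58 on 0 µM replicate 6 (others −3.93 to −3.66), HSD17B8 −0.83 on 0 µM replicate 2 (others −0.02 to 0.41) and HMOX1 1.09 on 20 µM replicate 5 (others 0.09 to 0.39).

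Among measures of array quality, the 75th percentile of the signal was 557.8 on 1 µM replicate 5 (others 386.9 to 445.3). The scanner software marked 656 spots as outliers on 0 µM replicate 1 (others 286 to 364), and the slope of the spike-in controls was 1.034 on 5 µM replicate 4 (others 1.09 to 1.101).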

How the results depend on the processing

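Leaving out the 4 arrays lowest on the first principal component and the covariates for shared variation were chosen after seeing the data, and the other settings before. Outside the arrays left out singly, the count of genes changed at 20 against 0 µM stayed within 1.5 times its value under 11 of 25 settings, was higher under 6 and lower under 8. For 20 against 5 µM, with 1 gene, these were 15, 3 and 6. The counts of 0 genes stayed 0 under 24 of 25 settings at 5 µM, all 25 at 1 µM and 22 of 24 for 5 against 1 µM, and a count of 0 cannot be lower. With the value table and RND3 aside, the text's called genes kept direction and call in 280 fits and kept the direction without the call in 179, and in 0 fits did the direction turn. These fits reuse the arrays on which the genes were chosen, so the lack of turns adds little. Genes that were not called kept their direction without a call in 1098 fits, gained a call in 21 and turned in 31, mostly genes near 0. The overlap of calls between doses was 0 in all 6 fits with the controls split, which says nothing about shared changes, since these fits called 0 genes at 5 µM and 0 or 1 at 1 µM. Slides and rows hold 1 to 3 arrays a dose, so the fits within them have few arrays, which limits what they can call. A signal not well above background is little more than a bound, which applies to MAPK4 and NEBL at 20 µM. No paired analysis was possible because the labels give no replicate numbers that would pair cultures. The sets of 1 slide and 1 row hold 1 array of each dose, except 1 set without 5 µM, and with these sets as a block 26 genes were called at 20 µM and 22 along the dose order. Except where said, the cause of a change was not tested.

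For 20 µM against 0 µM the count of 25 genes became 39 with slide as a random block, 78 with array weights, 16 with no filter on dim probes, 3 with slide, row and column as fixed effects and 3 with only the 2 groups compared. It was 0 within slide 1, slide 2, slide 3, row 1 and row 2, and 1288 with the value table. Without the 4 arrays it was 51, with the mitotic genes as a covariate 108 and with the first 3 residual components 976. That last value is no evidence, since 4 of 20 shuffles of the dose labels gave as many genes, with a median of 134.5 and a highest of 5376. Leaving out each array in turn gave 15 (without 0 µM replicate 1) to 29 (without 5 µM replicate 2). Of the named genes, LDHD lost the call without any 1 of 15 arrays (adjusted p 0.052 to 0.124) and SEMA4G of 11 (0.0505 to 0.109). HSPH1 lost it without 0 µM replicate 1 (0.0582) or 5 (0.0674) or 20 µM replicate 2 (0.0731), 3 (0.0621) or 4 (0.0693), SSH1 without 0 µM replicate 3 (0.0729) or 5 (0.0547) or 20 µM replicate 2 (0.073), and SHISA2 (0.0504) and NEBL (0.0505) without 0 µM replicate 1. SLC19A2 lost it without 0 µM replicate 1 (0.0518) or 20 µM replicate 2 (0.052), HAUS6 without 0 µM replicate 1 (0.0568) or 3 (0.0543) or 20 µM replicate 2 (0.052) or 4 (0.0515), and TMEM138 without any 1 of 11 arrays (0.0505 to 0.107). With median scaling the median log2 fold change of all genes was 0.0713, where it was −0.0138.

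For the trend the 29 genes became 18 with median scaling, 12 with no filter, 17 with slide, row and column, 0 within each slide and each row, 1417 with the value table and 110 with the mitotic covariate. Leaving out each array gave 14 (without 20 µM replicate 3) to 39 (without 0 µM replicate 6). For 20 against 5 µM the 1 gene became 0 with slide, row and column, within slides 1 and 3, within both rows and with only the 2 groups. It became 70 within slide 2, 2 with array weights and 3 with the mitotic covariate, and 1 to 2 without single arrays (2 without 5 µM replicate 5). For 5 against 0 µM the 0 genes became 44 within slide 2, and for 5 against 1 µM they became 1 within slide 1 and 77 within slide 2, where 5 µM has 1 array that is assumed to vary like the others. In these 2 comparisons and at 1 µM every single array left out gave 0.

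The 9 lists at 20 µM became 4 with the value table and 1 with an estimated correlation, and 6 to 10 without single arrays. The 3 lists at 5 µM became 6 with normexp, 5 with only probes well above background on all arrays, 8, 9 and 11 within slides 1, 2 and 3, 8 and 5 within rows 1 and 2, 10 with the value table, 1 with an estimated correlation and 5 with the mitotic covariate. Leaving out single arrays gave 3 to 9, with 5, 6, 9, 6 and 5 without 0 µM replicates 1, 2, 3, 4 and 6, and 9, 5, 5 and 6 without 5 µM replicates 1, 2, 3 and 5. The 4 lists at 1 µM became 1 with quantile normalisation, 2 with no filter, 1, 10 and 9 within the slides, 1 within row 1, 0 with an estimated correlation and 1 without the 4 arrays. Leaving out single arrays gave 2 to 10, with 2, 10, 9 and 2 without 0 µM replicates 1, 2, 3 and 5, and 10, 7 and 7 without 1 µM replicates 1, 4 and 5.

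Single lists turned in 15 fits, given here as adjusted p with a minus sign where the list is lower. Within slide 1, NRF2 targets at 5 µM gave −0.126. Within slide 2, NF-κB at 20 µM gave −0.889, NRF2 at 1 µM −0.516 and heat shock at 1 µM −0.564. Within slide 3, cholesterol at 20 µM gave 0.0204, interferon 0.252 and hypoxia at 5 µM 0.0231. With the value table, cholesterol gave 0.732, fatty acid synthesis 0.984, NRF2 −0.732 and ATF4 −0.253 at 20 µM, PPAR −0.0543, NRF2 −0.0362 and hypoxia 0.0543 at 5 µM, and PPAR −0.45 at 1 µM. PPAR at each dose, and NF-κB, hypoxia, fatty acid synthesis and NRF2 at 20 µM, kept their call without any single array.

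Lists lost the call without single arrays as follows, with the adjusted p. The ATF4 list at 20 µM gave 0.0747, 0.18 and 0.181 without 0 µM replicates 2, 5 and 6, and 0.137, 0.115, 0.0741 and 0.0661 without 20 µM replicates 1, 2, 3 and 5. NRF2 targets at 1 µM gave 0.0596 and 0.442 without 0 µM replicates 1 and 6, and 0.488 without 1 µM replicate 2. Heat shock genes at 1 µM gave 0.216, 0.205 and 0.188 without 0 µM replicates 1, 5 and 6, and 0.271 and 0.21 without 1 µM replicates 2 and 6. Oxidative phosphorylation at 1 µM gave 0.146, 0.205 and 0.748 without 0 µM replicates 4, 5 and 6, and 0.811, 0.062, 0.0515 and 0.0631 without 1 µM replicates 2, 3, 4 and 6.

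Log2 fold changes at 20 µM that turned, by setting, were these. Array weights gave GPX1 0.01 and MKI67 0.046, the mean of all probes MKI67 0.16, the mitotic covariate GPX1 0.00, and leaving out the 4 arrays GPX1 0.093. Median scaling gave NR5A1 0.01 and GPX1 0.085, and normexp SOD1 −0.01 and GPX1 0.02. Slide, row and column as fixed effects gave HMOX1 −0.067, SOD1 −0.012 and GPX1 0.045. Row 1 gave NR5A1 0.016, and row 2 HMOX1 −0.099, NQO1 −0.16, SOD1 −0.07 and GPX1 0.007. Slide 1 gave NR5A1 0.025, HMOX1 −0.35, NQO1 −0.10, SOD1 −0.089 and CDKN1A 0.23. Slide 2 gave NQO1 −0.092, SOD2 −0.20, GPX1 0.082 and MKI67 0.99. Slide 3 gave STAR 0.065, CYP11A1 0.15, HSD17B1 0.21, NR5A1 0.12 and SOD1 −0.049. Without single arrays, SOD1 ranged over −0.064 to 0.092, GPX1 over −0.078 to 0.058, MKI67 over −0.32 to 0.079 and NQO1 over −0.058 to 0.32.

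With the value table the turned values at 20 µM were ANGPTL4 −0.28, CPT1A −0.24, COL13A1 −0.05, CYP1A1 −0.27, XR_245037 0.19, SMIM29 −0.12, HAUS6 −0.015, FZD8 −0.033, HMGA1 −0.013, LGALS12 0.14, FAM167A −0.84, LNPK 0.03, SPOCD1 −0.13, SSH1 −0.26, CREB3L3 −0.30, CYP1B1 −0.20, TIPARP −0.053, IL1B −0.059, MYLIP 0.025, MAFG −0.17, TXN −0.049, GSR −0.16, PPP1R15A −0.28, HSPE1 −0.018, HSPB8 0.22, INHA 0.021, GATA4 0.056, KLF9 −0.078, NR5A1 0.049, HMOX1 −0.31, NQO1 −0.089, CAT −0.032 and SOD1 −0.35. At 5 µM they were ANGPTL4 −1.13, CPT1A −0.49, ACAA2 −0.068, TBC1D32 0.49 and SH3GL3 0.061. At 1 µM they were TTC41P 0.051 and TBC1D32 0.26. Of the 23 columns, 21 hold another array than their names say, which is the construction of this alternative.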

Other observations

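The counts over other splits of the arrays were planned, while the other tests in this part, and the expectations written for every test, were set only after the results were seen.

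Further genes changed at 20 µM, named here after their values were seen, were the thiamine transporter SLC19A2 (1.68-fold), the collagen gene COL13A1 (1.48-fold), SMIM29 (1.57-fold), TMEM138 (1.48-fold) and HAUS6 (1.43-fold), a part of the augmin complex of the spindle, all higher. SLC19A2 was not called without 0 µM replicate 1 (adjusted p = 0.0518) or 20 µM replicate 2 (adjusted p = 0.052), HAUS6 without any 1 of 4 arrays (adjusted p 0.0515 to 0.0568) and TMEM138 without any 1 of 11 (0.0505 to 0.107). PDK4, a kinase that restrains pyruvate oxidation and is outside the rule for named genes, was also chosen after its values were seen. It had a log2 fold change of 1.00 ± 0.31 at 20 µM, which passed over the PPAR list alone (limma, adjusted p = 0.0136) and not over all genes (adjusted p = 0.304). Along the dose order, and also named after their values were seen, the cytokine IL20 rose by 0.52 ± 0.10 per step on the log2 scale (adjusted p = 0.0325) and the growth factor GDNF by 0.25 ± 0.05 (adjusted p = 0.0358). The atypical cadherin FAT1 fell by 0.19 ± 0.04 per step (adjusted p = 0.0498), RNF145, a sterol-responsive ubiquitin ligase, fell by 0.18 ± 0.03 (adjusted p = 0.0294) and SH3GL3 fell by 0.14 ± 0.03 (adjusted p = 0.0281).

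Other splits of the arrays bear on whether chance can be excluded. For 20 µM against 0 µM, 1 of 100 splits, the real one, gave 25 or more genes, and the highest other gave 0. Chance is therefore unlikely for that count, and for the 1 gene between 5 and 20 µM (1 of 100, highest other 0), but it is not excluded. The splits take all arrays as interchangeable, which arrays in sets of 1 per dose would not be. Splits that mix the doses also count any change with dose as spread. At an unadjusted p under 0.05 (limma) the real split at 20 µM gave 1530 genes, 81 of 100 splits gave that many or fewer, and the highest other gave 2779. For the 29 genes of the trend chance is unlikely but not excluded (2 of 100, the real one among them, highest other 61). 1 other order of the dose labels thus called more genes than the real one. For 5 µM, 1 µM and 5 against 1 µM the real count was 0, so all 100 splits gave as many, with highest others of 0, 0 and 4. For the number of lists shifted these splits do not exclude chance: 28 of 100 splits gave 9 or more lists at 20 µM (highest other 16), 84 gave 3 or more at 5 µM (highest other 18) and 78 gave 4 or more at 1 µM (highest other 17). At 20 µM, 87 of the splits differed in mitotic genes by more than the real one. Among all splits that differ in the mean of the mitotic list by at most 0.091, the difference between 20 and 0 µM, 2 of 58 gave 9 or more lists at 20 µM (highest other 9), 39 of 61 gave 3 or more at 5 µM (highest other 13) and 23 of 72 gave 4 or more at 1 µM (highest other 12). That limit was chosen after the values were seen, so whether chance explains the number of lists at 20 µM is left open.

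The PPAR and fatty acid oxidation list was higher at every dose, and 1 of 100 splits, the real one, put it as high at 20, 5 and 1 µM (−log10 of the camera p of the highest other split 4.97, 9.63 and 2.80, where the real values were 7.45, 16.9 and 4.63). Other splits put the list lower by as much as 6.34, 5.92 and 3.53 on the same scale, and counting both directions the real split was still the only 1 of 100 as far from 0. At 5 and 1 µM the real split had 83 and 59 genes at an unadjusted p under 0.05 (limma), where the medians of the others were 588 and 665. That narrow spread by itself lowers the camera p, so the rank among the splits decides less at these doses. At 1 µM the list was not called with an estimated correlation (adjusted p = 0.239), and within slides 2 and 3 its camera p was 0.325 and 0.516, with 9 of 17 genes higher on each. Slide as the cause is excluded by the list being higher within 3 of 3 slides at 20 µM. The place of the array on the slide is not excluded, since arrays of a dose lay at the same places on every slide. With slide, row and column in the fit the camera p at 5 µM was 3.21e-06, but these terms cannot separate a place from its dose. The arrays at 20 and 1 µM, which leave out the shared controls, argue against these as the only cause at 20 µM. The mean of the list was 0.10 to 0.40 on the arrays at 20 µM and −0.36 to 0.02 on those at 1 µM. The p of that comparison (1.95e-05 by limma's camera) decides less, since other splits of the 20 and 0 µM arrays reached a smaller camera p and no splits were run for it. A hypothesis, with place on the slide still open, is that the mixture activates PPAR or raises fatty acid supply in these cells. It may be read from ANGPTL4, CPT1A and ACAA2, though no other dose series or receptor assay was tested here. These arrays cannot separate PPAR activation from fatty acid supply. A PPAR antagonist given with the mixture would test the hypothesis, and a receptor assay in medium without fatty acids would separate them.

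Arrays of 1 dose differed widely in the mean of the mitotic list (SD 1.04 within a dose). Dose accounted for 0.1% of the variance between arrays, slide for 2.9%, row for 0.3% and column for 2.6%. These shares argue against each of them, taken singly, as the source, and their combinations were not tested. Dose accounted for as little of the variance in a share of 0.00098 of 100000 permutations of the dose labels, and for 1 µM against 0 µM 1 of 100 splits, the real one, gave as few genes as 59 at an unadjusted p under 0.05 (the median of the others was 665). The 4 arrays lowest on the first principal component were 1 per dose: 0 µM replicate 2, 1 µM replicate 2, 5 µM replicate 3 and 20 µM replicate 5. Their list means were 0.97 to 1.19 for cholesterol and 0.41 to 0.77 for interferon genes, where the other arrays reached at most 0.47 and 0.22. A candidate explanation is that the samples came in sets of cultures that each gave 1 array per dose and that the labels do not name, such as repeats of the experiment that differed in growth. No such set was used as a block, because building it from the values would group samples by an outcome. With the mean of the mitotic list as a covariate, 108 genes were called at 20 µM, and 1 of 100 splits gave as many (highest other 1), so the spread between arrays may hide changes that a known pairing would show.

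The value table under its own column names gave 1288 genes between the columns named 20 and 0 µM, with 0 of them among the 25 called from the scanner files. Its columns follow the scan order, so those named 0 µM hold 6 of the 8 arrays of slide 1 and those named 20 µM the 6 arrays at the end of the order, on slide 3. Slide is a candidate explanation for these genes: 94% had the same sign between arrays of slides 3 and 1 that these columns do not hold. The match of all 23 columns to the arrays in scan order argues against the doses as the table names them. Under the array titles 1 of 100 splits, the real one, gave 25 or more genes. That count does not exclude the doses of the table, since an effect of place on the slide could also give it. No biological explanation of this pattern was tested.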
